A study of Mus musculus with 9 samples.

How the data were processed

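RNA had been sequenced from 9 cultures of Large T antigen immortalized mouse embryonic fibroblasts, 3 clones in each of 3 groups, as described by the labels: Rev3l heterozygous with empty vector, Rev3l knockout with empty vector, and Rev3l knockout with the construct TR4-2. RNA was extracted from frozen pellets with DNase digestion, and libraries were made with a stranded mRNA kit, per the labels. The processing notes of the submitters name TopHat2 2.0.10, HTSeq 0.6.0, edgeR 3.8.6 and the mm10 genome, without their settings, and the strand setting of the counting is not stated.

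The deposited table holds 17346 genes, and its unit is treated as signal: per the submitters' processing notes and the file name the authors gave CPM (reads scaled to library size) on effective library sizes, made with edgeR. The column sums differ between libraries, and the factors implied by them have a product of 0.831. Every value was checked to be a whole multiple of its column's smallest step: 100% of values were whole reads within a tolerance of 1e-06 reads, with a largest deviation of 1.22e-09. The whole reads recovered in this way gave the depth per library, 35725891 to 40620242, and were used for the count-based tests. The precision this depth gives concerns counting error only, since sequenced fragments without molecular identifiers are not independent molecules. The table holds 26 genes at 0 in all libraries and 0 mitochondrial genes, so mitochondrial transcripts were not analysed here. No sample column was left unused. Gene identifiers were matched to a GENCODE M21 annotation, in which 17339 had a symbol and a position, 7 had none, and 16511 had the identical version.

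Genes above 1 CPM in at least 3 of the 9 libraries were tested (12614 genes). The main test was limma 3.58.1 in R 4.3.3 on log2(CPM + 0.5), with 3 group means in 1 fit of all 9 libraries, a mean trend of the variance and Benjamini-Hochberg adjustment within a contrast. Genes with an adjusted p below 0.05 are called. The contrasts were KO_EV versus HET_EV, KO_TR4-2 versus KO_EV, KO_TR4-2 versus HET_EV, and KO_EV versus the mean of HET_EV and KO_TR4-2. edgeR 4.0.16 (quasi-likelihood, TMM) and DESeq2 1.42.0 were run on the whole reads. Clones were treated as independent, and clone numbers were not used to pair groups.

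A total of 27 gene lists (731 genes) was tested in the 4 contrasts with camera at a preset correlation of 0.01, with camera at an estimated correlation and with fry, adjusted over the lists within a contrast. List means of log2(CPM + 0.5) per library were compared by exact two-sided permutation. The lists cover polymerase zeta subunits, the neighbours of Rev3l, translesion synthesis and damage bypass, Fanconi and homologous recombination, nucleic acid sensing, interferon-stimulated genes, class I antigen presentation, inflammatory and senescence-associated factors, NF-kB, p53 targets, S phase, G2 and M phase, extracellular matrix, contractile and TGF-beta genes, cholesterol synthesis, the integrated stress and unfolded protein response, NRF2 targets, Hox genes, imprinted genes, X inactivation and Y-linked genes, and markers of macrophages, endothelium, epithelium, muscle, cartilage and bone, adipocytes and neural cells. The groups, contrasts, main test, lists, alternatives and the rule for naming genes were set before the data were examined, and the interferon list was included because the study is known to concern it. The rule names Rev3l and the other polymerase zeta subunits. Per contrast it also names the 10 called genes with the largest increases and the 10 with the largest decreases (5 and 5 for the last 2 contrasts), with groups separated, a mean of at least 5 CPM in the higher group and no predicted or unnamed genes. It further names up to 4 members with the smallest p of each list, and the 10 genes called in opposite directions between KO_EV versus HET_EV and KO_TR4-2 versus KO_EV with the largest smaller change. Cdk19 and the chromosome 5 genes outside that rule were chosen after their values were seen.

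The tools were tested on simulated data of the same size, with 100 genes changed 2-fold and 100 changed 4-fold between KO_EV and HET_EV. limma recovered 22% of the first and 78% of the second with 3 unchanged genes called, edgeR 21% and 77% with 2, and DESeq2 50% and 90% with 45. Camera recovered an interferon list shifted by 1 log2 and called 0 other lists. The list was shifted as a whole, so this does not test camera where list members vary together between clones. It therefore cannot decide between the preset and the estimated correlation, on which the result for the real interferon list depends.

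Alternatives tried were pseudocounts of 0.1 and 2 CPM, a filter at 5 CPM and no filter, rescaling each library to an equal sum, quantile normalization, robust estimation, array weights, only the groups compared, edgeR, DESeq2, a minimum change of 2-fold, estimated correlation, fry, and leaving out each library in turn. Removal of the chromosome medians from each library was added after the data were seen.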

Results

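Messenger RNA was sequenced from untreated mouse embryonic fibroblasts immortalized with Large T antigen. Rev3l encodes the catalytic subunit of DNA polymerase zeta, which copies damaged DNA templates. The 9 libraries fall into 3 groups of 3 clones each. By its label the first group is heterozygous for the Rev3l deletion and carries an empty vector (HET_EV, clones 11, 4 and 8). The second is labelled as a Rev3l knockout with an empty vector (KO_EV, clones 15, 3 and 4). The third is labelled as a knockout that carries TR4-2, a REV3L expression construct (KO_TR4-2, clones 18, 21 and 8). Each library held between 35725891 (KO_EV clone 15) and 40620242 (KO_TR4-2 clone 8) counted reads, so 1 read corresponded to between 0.0257 and 0.0287 CPM (reads scaled to library size). Values below are mean CPM ± SD with n = 3 clones per group, and log2 changes are limma estimates with their adjusted p over 12614 tested genes unless another test is named.

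Rev3l (ENSMUSG00000019841.15, chromosome 10, 39732118 to 39875211, mm10) averaged 74.1 ± 14.7 CPM in HET_EV, 42.1 ± 4.06 in KO_EV and 75.8 ± 53.9 in KO_TR4-2 (n = 3 each). The 3 KO_EV clones, at 37.6, 45.5 and 43.1 CPM (1402 to 1713 reads), lay below every HET_EV clone (59.0 to 88.4 CPM, 2058 to 3439 reads). The difference of -0.79 log2 (SE 0.39) was not called by limma (adjusted p = 0.22). It passed the threshold when KO_TR4-2 clone 8 was left out of the fit, at an unchanged -0.79 (adjusted p = 0.024). In KO_TR4-2, clones 18 and 21 had 43.2 and 46.2 CPM and clone 8 had 138, and the neighbouring gene Cdk19 was also highest in clone 8 (158 CPM, against 61.3 and 58.1 in clones 18 and 21). Over 13 measured neighbours of Rev3l the mean of log2(CPM + 0.5) was 5.32 in clone 8, above all other libraries, and 3.55 and 3.65 in clones 18 and 21, below every HET_EV and KO_EV clone (4.28 to 4.51). The surroundings of Rev3l thus differed between the KO_TR4-2 clones in the same direction as Rev3l itself. KO_TR4-2 differed from KO_EV by 0.63 log2 (adjusted p = 0.46) and from HET_EV by -0.17 (adjusted p = 0.82). The counts cover the whole locus, so exons outside the deletion still contribute, and reads of the construct may or may not align to the mouse gene. These levels therefore cannot show whether the deletion or the construct is expressed as labelled, and the comparisons below take the groups by their labels. Of the other polymerase zeta subunits, Mad2l2 had 49.1 ± 4.78, 40.9 ± 11.0 and 50.8 ± 8.21 CPM in the 3 groups, Pold2 120 ± 16.0, 113 ± 14.8 and 90.6 ± 11.8, and Pold3 31.0 ± 5.90, 46.9 ± 4.51 and 36.0 ± 1.82. No subunit was called over all genes in any of the 4 contrasts by limma. Pold3 was 0.60 log2 higher in KO_EV than in HET_EV (adjusted p = 0.057) and was the 1 subunit called when adjusted over the list alone. This change was not adjusted for the shifts of whole chromosomes between these groups that are described below.

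**Figure D1:**
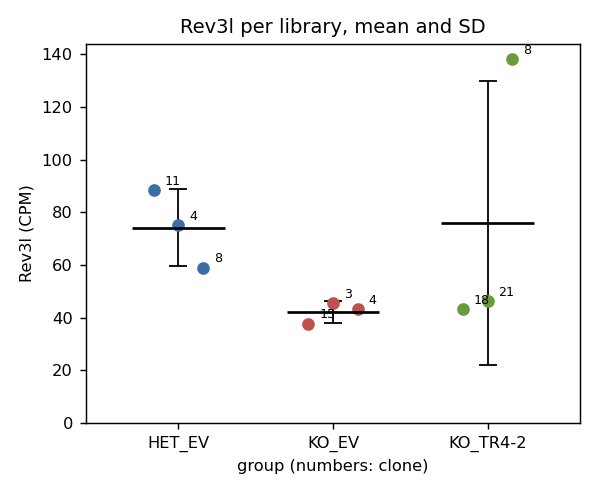
Rev3l level in CPM (vertical axis) for each library by group, with the clone number at each point and the group mean and SD. The KO_EV clones sit between 37.6 and 45.5 CPM, and KO_TR4-2 clone 8 stands apart from the other KO_TR4-2 clones at 138 CPM.

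The comparison of KO_EV with HET_EV addresses what differs in cells labelled as lacking Rev3l. Cdkn1c (ENSMUSG00000037664.13, chromosome 7, 143458339 to 143461050), which encodes a cyclin-dependent kinase inhibitor, fell from 173 ± 19.5 CPM in HET_EV to 0.143 ± 0.157 in KO_EV (n = 3 each, adjusted p = 2.9e-07) and stood at 0.0726 ± 0.0682 in KO_TR4-2. The amino acid transporter gene Slc38a4 fell from 211 ± 40 to 3.62 ± 1.56 CPM, a change of -5.73 log2 (SE 0.29, adjusted p = 8.3e-06). The Y-linked genes Ddx3y, Eif2s3y, Kdm5d and Uty stood at 152 ± 24.5, 144 ± 3.01, 65.4 ± 2.78 and 50.5 ± 0.458 CPM in HET_EV and at 0.143 CPM or less in KO_EV (adjusted p = 6.0e-07 or smaller). The keratin gene Krt18 (68.1 ± 39.9 CPM in HET_EV), Myo5c (35.0 ± 8.96), Irx1 (20 ± 4.28) and Hoxd8 (15.2 ± 4.59) were likewise near 0 in KO_EV, at 0.107, 0.313, 0.00886 and 0.00901 CPM. The transcription factor gene Tfap2a (ENSMUSG00000021359.16, chromosome 13, 40715302 to 40738376) rose from 0.159 ± 0.213 CPM in HET_EV to 30.1 ± 5.08 in KO_EV (adjusted p = 3.8e-05). Slc30a3 rose from 0.0996 to 46.3 ± 15.0 CPM (adjusted p = 0.0072), Col10a1 from 0.217 to 57.7 ± 62.4 (0.0015), Phactr2 from 0.0287 to 20.4 ± 8.80 (0.00051) and Sema3d from 0.507 to 34.8 ± 20.1 (0.0019). H2-Q6 rose from 0.559 ± 0.361 to 41.1 ± 23.7 CPM (adjusted p = 0.0035), with the reservation that the H2-Q genes are near-identical copies whose reads may be assigned to the wrong member. These 16 genes kept their call whichever library was left out. The other named genes did not: Bicc1 (0.254 ± 0.327 to 115 ± 60.9 CPM, adjusted p = 0.040) reached 0.11 without KO_EV clone 3, and Bmp2 (0.0345 to 30.6 ± 29.6, 0.015) reached 0.063 without KO_EV clone 4. Shroom2 (3.75 ± 6.15 to 51.3 ± 20.8 CPM, 0.025) reached 0.086 without KO_EV clone 4 and 0.14 with edgeR, and Trim30a (0.528 to 63.6 ± 91.2, 0.036) reached 0.092 without HET_EV clone 8. The fitted changes of genes near 0 in 1 group depend on the pseudocount, so levels are given for them.

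Interferon-stimulated genes were higher in KO_EV than in HET_EV as a group, with a median change of 2.18 log2 over the 67 measured members and 63 of them positive. Irf7, a transcription factor of the interferon response, rose from 1.37 ± 0.684 CPM in HET_EV to 78.7 ± 97.3 in KO_EV (4.70 log2, adjusted p = 0.0095, n = 3 each). Herc6 rose from 1.65 ± 0.477 to 28.8 ± 20.6 CPM (3.57 log2, SE 0.44, adjusted p = 0.0021), Lgals9 from 9.66 ± 6.74 to 118 ± 53.7 (3.70 log2, adjusted p = 0.0037) and the RNA sensor gene Dhx58 from 2.6 ± 0.534 to 43.7 ± 42.2 (3.43 log2, adjusted p = 0.0083). These 4 genes kept their call whichever library was left out. The list mean of log2(CPM + 0.5) was 2.75 ± 0.333 in HET_EV and 4.94 ± 1.39 in KO_EV, with clone 3 at 6.52, clone 4 at 4.41 and clone 15 at 3.89, all above the highest HET_EV clone (3.12). Of the 67 members, 30 were called higher and 0 lower over all genes, and 53 higher and 0 lower when adjusted over the list alone. The number called higher fell to 8 without HET_EV clone 11, 9 without HET_EV clone 8, 10 without KO_EV clone 4, 15 without HET_EV clone 4, and 18 or 19 without KO_TR4-2 clone 21, KO_TR4-2 clone 18 or KO_EV clone 3. With array weights 39 were called higher and 1 lower. The median was 1.40 without KO_EV clone 3. Of the 20 class I antigen presentation genes 19 lay higher in KO_EV: Tap1 rose from 13.1 ± 5.17 to 89.6 ± 30.1 CPM (2.74 log2, SE 0.32, adjusted p = 0.0017), Psmb8 from 0.978 ± 0.818 to 38.0 ± 22.8 (4.67 log2, 0.0021), H2-K1 from 115 ± 30.4 to 486 ± 129 (2.07 log2, 0.0027) and Erap1 from 26.1 ± 1.38 to 72.0 ± 17.1 (1.43 log2, 0.0031). Of these 20 genes, 13 were called higher over all genes and 15 when adjusted over the list alone, none lower, with a median of 1.49 log2. These 4 class I genes also kept their calls in all leave-one-out fits. In camera with a preset correlation of 0.01, adjusted p was 3.6e-17 for the interferon list and 2.1e-10 for class I presentation. With an estimated correlation neither passed (adjusted p = 0.47 and adjusted p = 0.33), and fry gave adjusted p = 0.056 and adjusted p = 0.0029. Fry tests whether the genes of a list move 1 way on balance and does not compare them with other genes. The exact two-sided permutation test of the list means gave p = 0.10 for both lists, the smallest that 3 against 3 clones allow.

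**Figure D2:**
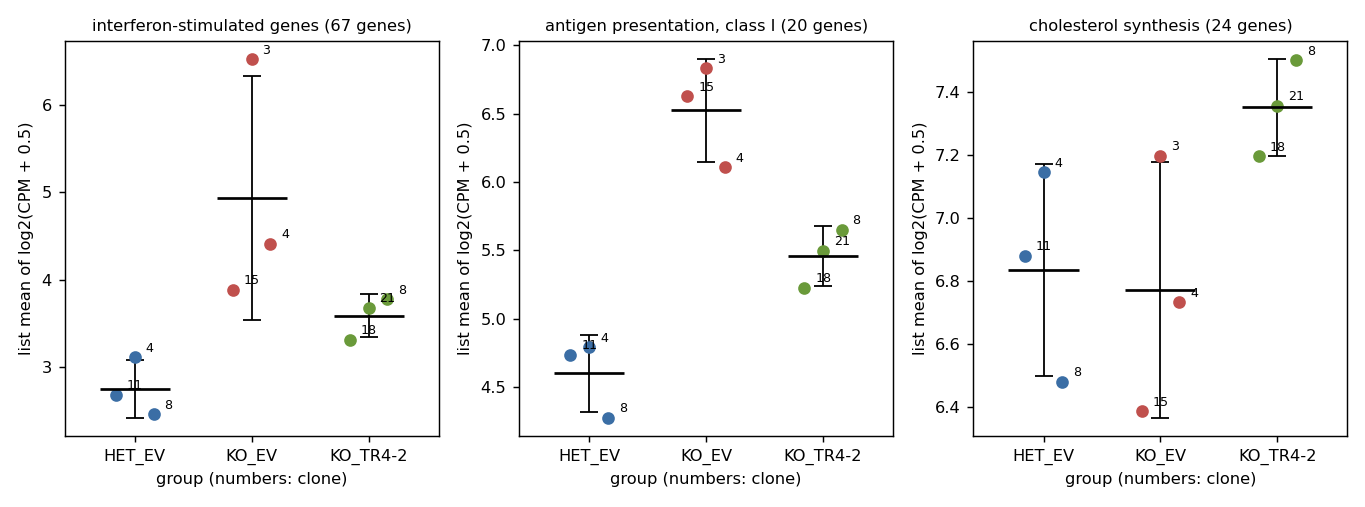
Mean of log2(CPM + 0.5) over the members of the interferon, class I presentation and cholesterol synthesis lists (vertical axis, 1 panel per list) for each library by group, with clone numbers and the group mean and SD. On the interferon list KO_EV clone 3 stands highest at 6.52, and the KO_TR4-2 clones, at 3.32 to 3.78, lie between HET_EV and KO_EV.

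Targets of p53 were higher in KO_EV as a group, with a median of 0.53 log2 and 32 of 38 positive. Bax, which encodes a promoter of apoptosis, rose from 39.3 ± 3.53 to 67.9 ± 4.91 CPM (0.78 log2, adjusted p = 0.013, n = 3), Plk3 from 9.98 to 22.4 ± 1.79 (adjusted p = 0.014), Tigar from 20.1 to 37.1 (0.88 log2, 0.017) and Mdm2 from 104 ± 13.1 to 186 ± 19.7 (0.84 log2, 0.041). Over all genes 5 targets were called higher (9 adjusted over the list alone) and 0 lower, and without KO_EV clone 4 the count was 0, with Bax at adjusted p = 0.052, Plk3 at 0.058 and Mdm2 at 0.13. Without KO_EV clone 3 the count was 1, with Tigar at adjusted p = 0.065, and it was 3 without HET_EV clone 11, KO_TR4-2 clone 18 or KO_TR4-2 clone 21 and 8 without KO_TR4-2 clone 8. Camera gave adjusted p = 1.3e-04 for the p53 list with the preset correlation, 0.42 with an estimated one and 0.048 in fry. All 3 groups were immortalized with Large T antigen, a protein that binds p53.

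Other signalling and proliferation genes also differed between KO_EV and HET_EV. The chemokine gene Ccl7 rose from 10.3 ± 2.69 to 60.6 ± 25 CPM (2.46 log2, adjusted p = 0.0085, n = 3), the DNA sensor gene Cgas from 15.9 ± 1.68 to 32.9 ± 4.73 (1.02 log2, 0.010), Tnip1 from 50.3 to 95.6 (0.91 log2, 0.0077) and Nfkbib by 1.16 log2 (0.0088). The lamin gene Lmnb1 fell from 229 to 139 CPM (-0.71 log2, adjusted p = 0.0090), and the call was lost with chromosome medians removed (adjusted p = 0.19), an alternative chosen after the data were seen. Lmnb1 was not alone in this. Over all contrasts, 40 results for named genes no longer passed with chromosome medians removed, 7 newly passed and 419 kept their side of the threshold. The 4 mitotic genes Kif20b (-0.77 log2, adjusted p = 0.019), Hjurp (-0.62), Kif20a (-0.89) and Cdc25b (-0.58) fell, each losing its call in some leave-one-out fits (largest adjusted p = 0.11, Cdc25b without KO_EV clone 4). By list, the counts called higher and lower over all genes, then adjusted over the list alone, were 2 and 1, then 9 and 2, of 26 inflammatory and senescence-associated factors. They were 2 and 0 on either adjustment for 18 NF-kB genes, 1 and 2, then 2 and 3, for 18 nucleic acid sensing genes, and 0 and 4, then 0 and 5, for 40 G2 and M phase genes. For 40 S phase genes limma called 0 on either adjustment, with a median of -0.19 log2 (-0.12 without HET_EV clone 11). With 1 library left out, the inflammatory genes called higher numbered 1 without KO_EV clone 3, KO_EV clone 4, KO_TR4-2 clone 18 or KO_TR4-2 clone 21, 4 without KO_EV clone 15 and 6 without KO_TR4-2 clone 8. Those called lower numbered 0 without HET_EV clone 4 or 8 and 2 without HET_EV clone 11 or KO_TR4-2 clone 8. The G2 and M phase genes called lower numbered 1 without HET_EV clone 11, HET_EV clone 4, KO_EV clone 3 or KO_EV clone 4, and 2 without KO_TR4-2 clone 18 or 21. Nucleic acid sensing genes called lower numbered 1 without HET_EV clone 4, any 1 KO_EV clone, or KO_TR4-2 clone 18 or 21, and 2 were higher without KO_EV clone 15. Of the S phase genes 3 were lower without KO_EV clone 15, 2 without HET_EV clone 8 and 1 without KO_TR4-2 clone 8. The NF-kB median was 0.58 without HET_EV clone 11, 0.53 without HET_EV clone 4 and 0.09 without HET_EV clone 8, and the G2 and M phase median -0.16 without KO_EV clone 15. In camera with the preset correlation the inflammatory (0.58 log2, adjusted p = 0.039), NF-kB (0.31, 0.041), G2 and M phase (-0.24, 0.014) and S phase (-0.19, 0.041) lists passed. None of these passed with an estimated correlation (adjusted p = 0.42, 0.60, 0.60 and 0.61), and in fry the inflammatory list did (adjusted p = 0.048) and the others did not (0.12, 0.12 and 0.19). Each also failed in some leave-one-out fits: the inflammatory list without HET_EV clones 11 or 8 or KO_EV clones 3 or 4 (largest adjusted p = 0.12), NF-kB without HET_EV clone 8 or KO_EV clone 3 (0.34), G2 and M phase without HET_EV clone 11 (0.15), and S phase without HET_EV clone 11 or KO_EV clones 3 or 4 (0.40). Nucleic acid sensing did not pass (0.36 log2, adjusted p = 0.37).

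Genes tied to cell identity and position differed as well. Hoxd9 stood at 12.7 ± 2.03 CPM in HET_EV and 0.00894 in KO_EV (adjusted p = 1.1e-05, n = 3), and Hoxd10 at 5.67 ± 0.515 and 0.00886 (5.0e-05), whereas Hoxa13 rose from 1.53 to 13.4 ± 5.33 CPM (2.82 log2, 0.0051). Among imprinted genes Impact rose from 18.7 ± 3.93 to 64.7 ± 1.20 CPM (1.78 log2, 0.0055) and Gnas fell by 0.63 log2 (0.027, and 0.10 without KO_EV clone 4). The matrix enzyme gene Loxl2 fell from 410 ± 128 to 64.4 ± 35.6 CPM (-2.80 log2, 0.0076), Col3a1 from 234 to 21.7 (-4.61 log2, 0.019, and 0.066 without KO_EV clone 3) and Fn1 from 5774 to 1910 (-1.65 log2, 0.039, and 0.13 without KO_EV clone 4). Over all genes the counts called higher and lower, then adjusted over the list alone, were 1 and 4, then 2 and 4, of 16 Hox genes, 1 and 2, then 2 and 4, of 14 imprinted genes, and 1 and 5, then 2 and 6, of 44 matrix genes. They were 0 and 4, then 1 and 4, of 5 X inactivation and Y-linked genes, 0 and 2, then 0 and 3, of 4 epithelial markers, and 0 and 1 on either adjustment of 10 neural markers (Mbp, -3.30 log2, adjusted p = 0.012, and 0.053 without KO_EV clone 4). The matrix genes called lower numbered 1 without HET_EV clone 4, HET_EV clone 8 or KO_EV clone 4, 2 without KO_EV clone 3 or KO_TR4-2 clone 18, 3 without KO_TR4-2 clone 21 and 8 without KO_EV clone 15. Those called higher numbered 0 without KO_EV clone 3 or 4 and 2 without HET_EV clone 8, KO_TR4-2 clone 21 or KO_TR4-2 clone 8. The imprinted genes called lower numbered 1 without KO_EV clone 3, KO_EV clone 4 or KO_TR4-2 clone 21, and 2 were higher without HET_EV clone 4. The epithelial markers called lower numbered 1 without HET_EV clone 8, KO_EV clone 15, KO_EV clone 4, KO_TR4-2 clone 18 or KO_TR4-2 clone 21. Of the Hox genes 2 were higher without HET_EV clone 11, and of the X and Y list 1 was higher without KO_EV clone 15. Camera with the preset correlation passed the X and Y list (adjusted p = 9.4e-10, and 0.034 with an estimated correlation, the only list to pass so), the epithelial list (median -2.55 log2, 0.031, estimated 0.33) and the neural list (-1.14 log2, 0.031, estimated 0.42). The epithelial list failed without KO_EV clone 15 or HET_EV clone 8 (largest adjusted p = 0.079), the neural list without HET_EV clone 8 (0.10). The Hox list (median -0.06 log2, adjusted p = 0.072), the imprinted list (-0.17, 0.24) and the matrix list (-0.27, 0.083) did not pass in camera. With 1 library left out the matrix list passed without HET_EV clone 11 (-0.65 log2, adjusted p = 0.0096) and KO_EV clone 15 (-0.23, 0.044), and its median was -0.17 without HET_EV clone 8. The Hox list passed without HET_EV clone 4 (-0.12, 0.033), and its median ran from -0.25 without HET_EV clone 8 to -0.011 without HET_EV clone 11. The imprinted median ran from -0.57 without HET_EV clone 4 to -0.11 without KO_EV clone 3, and the neural median was -0.64 without HET_EV clone 8. Fry passed the Hox (adjusted p = 1.4e-04, mean change -0.94 log2), imprinted (0.019, mean -1.06), X and Y (7.8e-10) and epithelial (2.3e-04) lists, and not the matrix (0.29) or neural (0.052) list. Fry passed the Hox (1.2e-04) and imprinted (0.025) lists in KO_TR4-2 against HET_EV as well. However, the imprinted list mean of KO_TR4-2 clone 8 (4.49) lay within HET_EV (4.14 to 4.67), with clones 18 and 21 at 2.99 and 2.57. The imprinted median there turned from -0.21 to 0.053 log2 without KO_TR4-2 clone 21, and exact two-sided permutation of the list means gave p = 0.30.

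The remaining lists did not pass in camera for KO_EV against HET_EV. The gene changes in these lists were not adjusted for shifts of whole chromosomes. The medians of such shifts reached 0.46 log2 on chromosome 7, -0.44 on chromosome 12 and -0.42 on chromosome 18. Damage tolerance genes had few calls: Poli, a translesion polymerase gene, fell from 12.9 to 7.02 CPM (-0.85 log2, adjusted p = 0.048, n = 3, and 0.12 without HET_EV clone 4), and Fancm (-0.88 log2, 0.037), Fanca (-0.78, 0.038) and Exo1 (-0.52, 0.042) fell, with adjusted p of 0.096 and 0.094 without HET_EV clone 11 and 0.13 without KO_EV clone 3. These were 1 of 25 translesion and bypass genes (0 adjusted over the list alone, camera adjusted p = 0.15) and 3 of 41 Fanconi and recombination genes (3, camera 0.37). The contractile and TGF-beta list had 1 of 25 called higher (0 adjusted over the list alone, camera 0.59), which was Id1 (15.8 to 118 CPM, adjusted p = 0.038, and 0.094 without HET_EV clone 11). The NRF2 list had 2 of 25 called higher (2, camera 0.76), Blvrb (1.23 log2) and Taldo1 (0.76 log2), and its median of -0.09 log2 differed in sign from its camera direction. The cartilage and bone list had Col10a1 called higher and Spp1 lower (-2.29 log2, adjusted p = 0.0092) of 5, the same counts adjusted over the list alone (camera 0.59). Limma called 0 members on either adjustment in cholesterol synthesis (24 genes, camera adjusted p = 0.76), the integrated stress and unfolded protein response (29, 0.70), the neighbours of Rev3l (13, 0.58), and macrophage (3, 0.15), endothelial (3, 0.58), muscle (1, 0.55) and adipocyte (4, 0.25) markers. The 3 measured macrophage and blood cell markers, Cd14, Cd68 and Coro1a, had a list mean of 2.10 ± 0.655 in HET_EV, 3.18 ± 0.199 in KO_EV and 2.70 ± 0.197 in KO_TR4-2. All KO_EV clones lay above all other clones, as on the interferon list, and exact two-sided permutation gave p = 0.10 against either group. For the 4 polymerase zeta subunits camera gave adjusted p = 0.82. The translesion count was 0 whichever library other than KO_TR4-2 clone 8 was left out, and without that clone 2 were higher. The Fanconi count was 0 in all leave-one-out fits but those without HET_EV clone 4 or KO_TR4-2 clone 8, and 1 was higher without the latter. The contractile count was 0 without HET_EV clone 11, KO_EV clone 15, KO_EV clone 4 or KO_TR4-2 clone 18 and 2 without KO_TR4-2 clone 8, with 1 lower without KO_EV clone 15. The NRF2 count was 0 without HET_EV clone 11, HET_EV clone 4, KO_EV clone 15 or KO_TR4-2 clone 21 and 1 without HET_EV clone 8, KO_EV clone 4 or KO_TR4-2 clone 18, with 1 lower without HET_EV clone 11, HET_EV clone 8 or KO_EV clone 15. Cholesterol synthesis had 2 higher without KO_EV clone 15 and 1 without KO_TR4-2 clone 8. The stress response had 1 higher and 3 lower without HET_EV clone 11, 1 and 1 without KO_EV clone 15, and 2 and 2 without KO_TR4-2 clone 8, and the neighbours of Rev3l had 1 lower without KO_TR4-2 clone 8.

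Over all genes limma called 1235 between KO_EV and HET_EV, 724 higher and 511 lower in KO_EV, of which 763 changed at least 2-fold, and 3517 had an unadjusted p under 0.05. Of all 12614 tested genes, which are not independent of each other, 4189 (33.2%) had all clones of 1 group beyond all clones of the other, where chance gives 10%. The count was 397 without KO_EV clone 4, 566 without KO_EV clone 3, 640 without HET_EV clone 4, 793 without HET_EV clone 8 and 802 without KO_TR4-2 clone 18. With each library rescaled to an equal sum, which moved the median gene by 0.10 log2 (from -0.0067 to 0.095), 1027 were called higher and 366 lower, so the share called higher moved from 58.6% to 73.7%. HET_EV was the only group with Y-linked transcripts above background, so the groups also differ in sex-linked content, and neither this comparison nor that of KO_TR4-2 with HET_EV separates the origin of the clones from genotype.

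The comparison of KO_TR4-2 with KO_EV addresses what differs in knockout cells labelled as carrying the REV3L construct, of which clones 18 and 21 had Rev3l at 43.2 and 46.2 CPM, against 37.6 to 45.5 in KO_EV. Dbf4 (ENSMUSG00000002297.16, chromosome 5, 8396973 to 8422716), which encodes the activator of the replication kinase Cdc7, rose from 154 ± 19.4 CPM in KO_EV to 627 ± 28.8 in KO_TR4-2 (2.03 log2, SE 0.14, adjusted p = 0.0015, n = 3 each). Tom1l1 (ENSMUSG00000020541.12, chromosome 11, 90643465 to 90688366) fell from 7.72 ± 2.79 to 0.0997 ± 0.0633 CPM (adjusted p = 0.0045), against 25 ± 5.58 in HET_EV. These were the only genes of the largest changes that kept their call whichever library was left out (largest adjusted p = 0.020 and 0.042). The drug efflux gene Abcb1b rose from 46.5 ± 12.7 to 208 ± 93.3 CPM (2.10 log2, SE 0.34, adjusted p = 0.038), Crot from 52.1 ± 7.68 to 194 ± 52.3 (1.86 log2, 0.016), Sri from 89.4 ± 4.84 to 332 ± 109 (1.84 log2, 0.014) and Pcdh19 from 48.8 ± 17.1 to 163 ± 5.32 (1.79 log2, 0.025). Tmeff2 (2.46 log2, 0.047), Peg13 (2.32, 0.029), Tmem243 (2.02, 0.027), Slc25a40 (1.75, 0.014) and Lhx2 (1.56, 0.038) also rose. Klhl22 fell from 61.5 ± 17.1 to 4.33 ± 3.57 CPM (-4.14 log2, 0.038), Sorl1 from 22.8 ± 11.4 to 0.748 ± 0.549 (-4.17, 0.025), Tspan7 from 18.0 ± 7.24 to 0.417 ± 0.676 (-4.51, 0.014) and the kinase gene Lyn from 9.45 ± 1.72 to 0.344 ± 0.305 (-3.61, 0.014). Phactr2 (-3.96 log2, 0.016), H2-Q6 (-4.38, 0.038), Gramd1b (-4.19, 0.025), Lmcd1 (-3.86, 0.027) and Pcdh17 (-3.79, 0.024) fell as well. Each of these other 18 lost its call in at least 1 leave-one-out fit, with the largest adjusted p between 0.066 (Sri and Tspan7, without KO_EV clone 4) and 0.19 (Tmeff2, without KO_TR4-2 clone 18). Limma called 69 genes, 23 higher and 46 lower in KO_TR4-2, 61 of them at least 2-fold, and 2059 had an unadjusted p under 0.05. Of all 12614 tested genes 3165 (25.1%) had the clones of the groups apart, where chance gives 10%. edgeR called 26 (12 higher, 14 lower) and DESeq2 759 (330 higher, 429 lower), so the share called higher was 33.3% with limma, 46.2% with edgeR and 43.5% with DESeq2. The count was 2 without KO_TR4-2 clone 21, 3 without KO_EV clone 4, 4 without KO_EV clone 3, 5 without KO_TR4-2 clone 18, 39 without HET_EV clone 4 and 175 without KO_TR4-2 clone 8.

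In KO_TR4-2 the interferon-stimulated genes lay lower than in KO_EV in 65 of 67 members, with a median of -1.27 log2, but limma called 0 of them over all genes and 0 adjusted over the list alone. The smallest p belonged to Xaf1 (43.4 ± 49.1 CPM in KO_EV, 4.95 in KO_TR4-2, adjusted p = 0.15), Ifi35 (78.4 ± 35.6 and 36.3, 0.15), Ccl5 (28.8 and 6.37, 0.16) and Dhx58 (43.7 ± 42.2 and 9.10 ± 3.23, 0.17). The median was -0.36 log2 without KO_EV clone 3. All 20 class I presentation genes lay lower, with a median of -0.63 log2, and H2-Q6 was the 1 called over all genes (9 adjusted over the list alone), with 3 called lower without KO_TR4-2 clone 8 and 0 without any other library but HET_EV clone 8. H2-K1 went from 486 ± 129 to 230 ± 51.2 CPM (-1.06 log2, adjusted p = 0.13). All 24 cholesterol synthesis genes lay higher in KO_TR4-2, with a median of 0.62 log2 and 0 called over all genes (2 adjusted over the list alone): Mvk went from 92.0 ± 4.98 to 154 ± 9.88 CPM (0.74 log2, adjusted p = 0.11) and Acat2 from 147 ± 17.8 to 227 ± 14.1 (0.63 log2, 0.11). Of 38 p53 targets 33 lay lower (median -0.33 log2, 0 called over all genes, 2 adjusted over the list alone), with Mdm2 at 186 ± 19.7 and 94.7 ± 25.7 CPM (-1.0 log2, adjusted p = 0.096). Of 40 S phase genes 29 lay higher (median 0.22 log2, 0 called on either adjustment). Camera with the preset correlation passed these 5 of 27 lists (adjusted p = 1.4e-12, 2.3e-07, 2.4e-07, 3.2e-04 and 0.014), none passed with an estimated correlation (adjusted p = 0.85 for each), and fry passed none (0.29 for class I presentation, 0.53 for the other 4). The p53 list reached adjusted p = 0.055 without KO_TR4-2 clone 8, and the S phase list 0.12 without KO_EV clone 3. Exact two-sided permutation of the list means gave p = 0.10 for the interferon list and p = 0.20 for cholesterol synthesis, and 3 against 3 cannot go below 0.10. Outside these lists Ccl7 fell from 60.6 ± 25 to 11.7 ± 5.71 CPM (-2.35 log2, adjusted p = 0.045, and 0.18 without KO_EV clone 4).

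A run of neighbouring genes on chromosome 5 (8046078 to 9161776, mm10, 1116 kb) was higher in KO_TR4-2. It holds 10 tested genes, and its edges, with the genes Adam22, Rundc3b, Abcb1a and Dmtf1, were chosen after the values were seen. Of the 23 genes called higher in KO_TR4-2 than in KO_EV, 7 lie in it: Sri, Dbf4, Slc25a40, Abcb1b, Crot, Tmem243 and Dmtf1 (2.48-fold, the smallest fold of the 10). In 9 of the 10 every KO_TR4-2 clone lay above all other libraries (n = 3 against 6), the exception being Adam22, the largest fold at 6.50 but low in KO_TR4-2 clone 8 (0.772 CPM). The median change over the 10 genes was 1.97 log2. Relative to the HET_EV mean, the block median was 2.49, 2.50 and 2.48 log2 in KO_TR4-2 clones 18, 21 and 8, and 0.39, 0.14 and 0.51 in KO_EV clones 15, 3 and 4. The 23 tested genes within 5 Mb on the left had a median of 0.17 log2 and the 5 on the right 0.97, with the nearest tested gene on the right, Gm7332 (start 9260935), at -0.14 log2. Outside the block the clones of KO_TR4-2 lay above those of KO_EV in Cfap69 (1.54-fold) and Steap2 (1.82-fold) on the left. On the right they did so in Sema3a (2.43-fold, start 13125414) and Gm43719 (2.89-fold, start 13604035), and Sema3e (start 14025276) was at -1.18 log2. Of the called genes, Dbf4 alone of the 6 that the naming rule covers kept its call in all leave-one-out fits, the others reaching adjusted p = 0.066 (Sri, without KO_EV clone 4) to 0.14 (Abcb1b, without KO_EV clone 3).

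**Figure D3:**
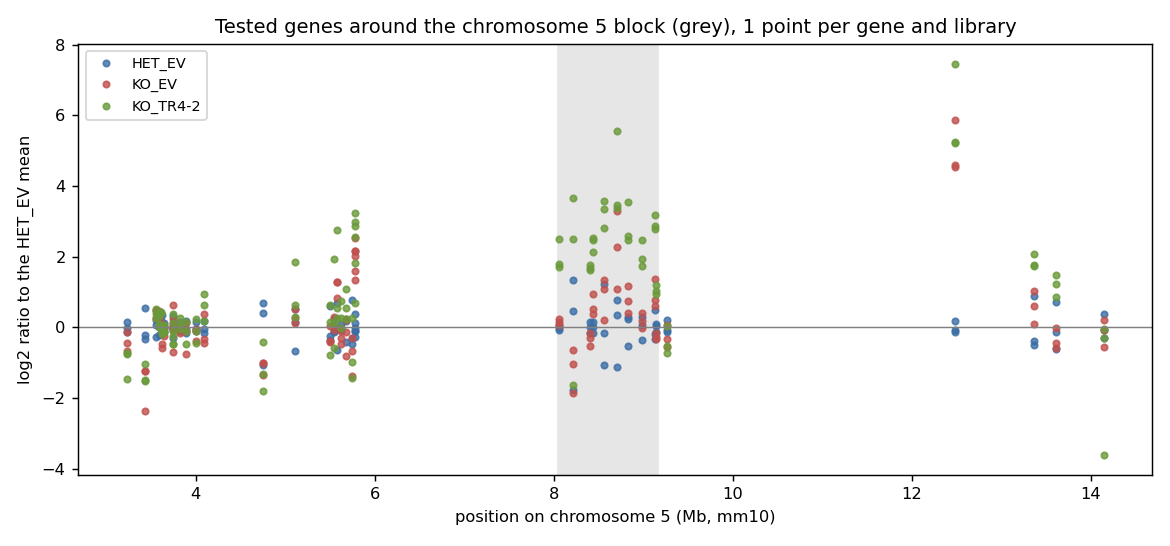
Log2 ratio to the HET_EV mean (vertical axis) against position on chromosome 5 in Mb (mm10), 1 point per tested gene and library, coloured by group, with the block of 10 genes in grey. Inside the block the KO_TR4-2 medians lie between 2.48 and 2.50 log2, and those of KO_EV between 0.14 and 0.51.

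Genes that differed between KO_EV and HET_EV and moved back in KO_TR4-2 address which changes the construct goes with. Dysf, a membrane repair gene, rose from 3.29 ± 1.17 CPM in HET_EV to 40.9 ± 9.54 in KO_EV (3.47 log2, SE 0.46, adjusted p = 0.0031) and fell to 5.69 ± 4.15 in KO_TR4-2 (-2.93 log2, SE 0.46, 0.036; n = 3 each). Phactr2 stood at 0.0287, 20.4 ± 8.80 and 0.896 ± 0.692 CPM in the 3 groups, Pcdh17 at 0.0428, 13.9 ± 9.67 and 0.481 ± 0.426, Limch1 at 0.115, 8.99 ± 5.05 and 0.508, and the glutathione transferase gene Mgst1 at 0.491, 12.3 ± 5.78 and 0.963. Elfn1, Trp53i11, Pla1a, H2-Q5 and H2-Q6 followed the same course. The return fell out of the call for all 10 in at least 1 leave-one-out fit, with the largest adjusted p from 0.078 (Phactr2, without KO_EV clone 3) to 0.21 (Trp53i11, without KO_EV clone 4). Pla1a was also no longer called higher in KO_EV without HET_EV clone 4 (adjusted p = 0.050). In all, 38 genes were called in opposite directions, 29 higher then lower and 9 lower then higher, and 3 in the same direction. Independent lists of these sizes would share 2.64 and 0.93, but these contrasts share the KO_EV libraries and are not independent. In 100 simulations of unchanged groups that share these libraries the opposite calls had a mean of 0.11 and a maximum of 11. The median simulation had 0 calls in either contrast (means 25.6 and 14.9, maxima 2551 and 1483), so this is not a level for groups that do differ. Across genes, which are not independent replicates, the changes correlated at r = -0.34, against a mean of -0.47 in these simulations. The simulated groups do not differ, and real differences can move r either way. The 2 correlations therefore cannot decide how much this sharing gives. The covariance was -0.17, stronger than the simulated mean of -0.06 but within the simulated range (-0.37 to 0.095), so it does not show a return beyond this sharing. The 38 became 0 without KO_EV clone 4 or KO_TR4-2 clone 21, 1 without KO_TR4-2 clone 18, 2 without KO_EV clone 3, 10 without HET_EV clone 4, 25 without HET_EV clone 11, 59 without KO_EV clone 15 and 83 without KO_TR4-2 clone 8. Splitting the 3 clones of KO_EV to give each contrast its own controls would leave 1 contrast with 1 clone, and was not done.

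The comparison of KO_TR4-2 with HET_EV addresses what still differs from HET_EV in knockout cells labelled as carrying the construct. The X inactivation RNA Xist (ENSMUSG00000086503.4, X chromosome, 103460366 to 103483254) rose from 0.216 ± 0.261 CPM in HET_EV to 306 ± 40.2 in KO_TR4-2 (adjusted p = 0.0090, n = 3 each), with 42.2 ± 38.4 in KO_EV. Lmx1b, a limb patterning gene, rose from 0.0460 ± 0.0346 to 22.5 ± 4.94 CPM (adjusted p = 1.0e-05), Tfap2a from 0.159 ± 0.213 to 33.4 ± 14.8 (3.0e-05), Sema3d from 0.507 to 83.7 ± 80.9 (0.00062) and Bmp2 from 0.0345 to 35.7 ± 22.8 (0.0088). Cdkn1c, Ddx3y, Eif2s3y and Kdm5d fell to 0.0726 CPM or less, from 173 ± 19.5, 152 ± 24.5, 144 ± 3.01 and 65.4 ± 2.78. The basement membrane gene Col4a1 went from 776 ± 284 to 49.2 ± 83.9 CPM (-7.05 log2, SE 1.81, adjusted p = 0.046), but reached 0.14 without KO_TR4-2 clone 21 and 0.21 with edgeR. Of the interferon list, Lgals9 (3.21 log2, 0.0075) and Herc6 (2.35 log2, 0.014, and 0.051 without KO_TR4-2 clone 18) were higher in KO_TR4-2 than in HET_EV, 2 of 67 on either adjustment with a median of 0.86 log2 and 60 positive. Of class I presentation genes 7 of 20 were higher (9 adjusted over the list alone, median 0.86 log2), among them Tap1 (1.76 log2, 0.013) and Nlrc5 (2.96 log2, 0.012), and of cholesterol synthesis genes 3 of 24 (4), Mvk (1.11 log2, 0.0055), Ebp (0.72, 0.028) and Acat2 (0.57, 0.037). The class I count was 1 without KO_TR4-2 clone 21, 2 without KO_TR4-2 clone 18, 3 without HET_EV clone 8 and 4 without HET_EV clone 11, and the interferon count was 10 without KO_EV clone 3 and 1 without KO_TR4-2 clone 18 or 21. The cholesterol synthesis count was 1 without HET_EV clone 8, KO_EV clone 4, KO_TR4-2 clone 18 or KO_TR4-2 clone 21, and its median went from 0.51 to 0.26 log2 without HET_EV clone 8. Ebp reached adjusted p = 0.12 and Acat2 0.14 without KO_TR4-2 clone 21. Camera with the preset correlation passed 6 of 27 lists: interferon (adjusted p = 2.5e-04), class I presentation (8.5e-04), cholesterol synthesis (5.6e-04), G2 and M phase (0.014), X and Y (1.5e-08) and epithelial (0.0024). With an estimated correlation adjusted p was 0.79 for the first 4, 0.043 for X and Y and 0.16 for the epithelial list. Fry passed the X and Y (7.5e-10) and epithelial (1.2e-04) lists and none of the first 4 (0.42, 0.099, 0.20 and 0.20). G2 and M phase reached 0.22 without HET_EV clone 11 (median -0.12 log2, against -0.25). Limma called 1063 genes, 574 higher and 489 lower in KO_TR4-2, 703 of them at least 2-fold, with 3372 at an unadjusted p under 0.05. Of all 12614 tested genes 4187 (33.2%) had the clones of the groups apart, where chance gives 10%. The count was 402 without KO_TR4-2 clone 21, 458 without KO_TR4-2 clone 18, 667 without HET_EV clone 8, 685 without HET_EV clone 4 and 701 without KO_EV clone 4. Of the calls, 555 were shared in direction with KO_EV against HET_EV and 2 were opposite. Independent lists would share 52.8, but both contrasts use the HET_EV libraries. In 100 simulations of unchanged groups that share HET_EV the mean was 0.01 and the maximum 1, but the median simulation had 0 calls between KO_EV and HET_EV, so this is not a level for groups that do differ. Across genes, which are not independent replicates, the changes correlated at r = 0.76, against a mean of 0.51 (at most 0.98) in these simulations. Their covariance was 0.55, against a mean of 0.072 (at most 0.61). Both lay above the simulated mean and below the largest simulated value. Sharing the HET_EV libraries is thus neither excluded nor shown as their source. Of the 1235 genes called between KO_EV and HET_EV, 878 lay closer to KO_EV in KO_TR4-2 and 357 closer to HET_EV.

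The last comparison sets KO_EV against the mean of HET_EV and KO_TR4-2, 3 clones against the 6 labelled as having a REV3L allele or construct, although KO_TR4-2 clones 18 and 21 had Rev3l at 43.2 and 46.2 CPM, against 37.6 to 45.5 in KO_EV. Phactr2 (4.58 log2, adjusted p = 0.0014), Pcdh17 (4.16, 0.0025) and H2-Q6 (4.79, 0.0063) were higher in KO_EV, and the protocadherin gene Pcdhgb7 was lower (13.2 ± 3.65, 0.223 ± 0.0309 and 0.677 ± 0.289 CPM in HET_EV, KO_EV and KO_TR4-2, 0.0029). These 4 kept their call whichever library was left out. H2-Q7 (4.33 log2, 0.021) and Irf7 (3.52, 0.031) were also higher, and Sorcs2 (-4.08, 0.0087), Nfatc4 (-3.38, 0.022), Dock8 (-2.84, 0.015) and Syce2 (-2.74, 0.014) lower. Without KO_EV clone 4, adjusted p was 0.076 for H2-Q7, 0.092 for Irf7, 0.12 for Nfatc4, 0.086 for Dock8 and 0.078 for Syce2, and without KO_EV clone 3 it was 0.052 for Sorcs2. Sorcs2 stood at 102 ± 48.4 CPM in HET_EV, 2.99 ± 0.762 in KO_EV and 49.3 ± 47.4 in KO_TR4-2. Of the interferon list 11 of 67 were called higher and 0 lower (48 and 0 adjusted over the list alone, median 1.71 log2, 0.93 without KO_EV clone 3, 65 positive), and the count was 1 without HET_EV clone 11, KO_EV clone 4, KO_TR4-2 clone 18 or KO_TR4-2 clone 21, 2 without HET_EV clone 4 or KO_EV clone 3, 3 without HET_EV clone 8 and 19 without KO_EV clone 15. Of class I presentation genes 10 of 20 were higher (17 adjusted over the list alone, median 1.05 log2, all 20 positive), and 1 without KO_EV clone 3, 5 without KO_EV clone 15, KO_EV clone 4 or KO_TR4-2 clone 18 and 6 without KO_TR4-2 clone 21. Exact two-sided permutation of the list means over 84 splits gave p = 0.012 for both lists and p = 0.024 for the p53 list (Mdm2 and Tigar higher of 38, 3 adjusted over the list alone). These splits treat the other 6 clones as alike, although HET_EV and KO_TR4-2 differ. The X and Y list, whose Y-linked genes HET_EV alone expressed above background, gave an exact permutation p = 0.024 as well. Its list means were -0.77 to 0.62 in KO_EV, 0.87 to 0.98 in KO_TR4-2 and 5.06 to 5.21 in HET_EV. KO_EV thus lay below both groups, but far closer to KO_TR4-2. Such a p compares KO_EV with the other 6 clones pooled and does not show how far it differs from each group. The p53 count was 1 without HET_EV clone 4 and 0 without HET_EV clone 11, any 1 KO_EV clone, or KO_TR4-2 clone 18 or 21. Mdm2 reached adjusted p = 0.16 without KO_EV clone 4 and Tigar 0.17 without KO_EV clone 3. Camera with the preset correlation passed 7 lists, these 3 with adjusted p = 8.1e-20, 6.0e-12 and 3.9e-06 (0.39, 0.33 and 0.39 with an estimated correlation). The others were X and Y (9.1e-12, estimated 0.021), cholesterol synthesis (median -0.36 log2, 0.0074, estimated 0.58), S phase (-0.23, 0.0086, estimated 0.58) and neural markers (-0.83, 0.020, estimated 0.39). Fry passed class I presentation (0.0070), the p53 list (0.0499), X and Y (2.9e-07), Hox genes (0.0040, camera 0.079) and epithelial markers (0.0091, camera 0.14), and not the interferon (0.085), cholesterol synthesis (0.34), S phase (0.20) or neural (0.085) list. Cholesterol synthesis reached 0.34 without KO_EV clone 15 (median -0.15 log2), and its median was -0.58 without KO_EV clone 3. S phase reached 0.071 without HET_EV clone 11 and 0.056 without KO_EV clone 3, and neural markers 0.098 without HET_EV clone 8 and 0.065 without KO_EV clone 15. Limma called 366 genes, 218 higher and 148 lower, 231 at least 2-fold and 2712 at an unadjusted p under 0.05. In 89 of the 366 the KO_EV clones did not lie beyond all other clones, and over all 12614 tested genes they did in 1121 (8.89%), where chance gives 2.38%. With each library rescaled to an equal sum, which moved the median gene by 0.071 log2, they were 355 and 133, moving the share called higher from 59.6% to 72.7%. The count was 71 without KO_EV clone 3, 77 without KO_EV clone 4, 140 without KO_TR4-2 clone 18, 142 without KO_TR4-2 clone 21, 189 without HET_EV clone 4 and 661 without KO_TR4-2 clone 8. The contrast also calls genes set by HET_EV alone, such as the Y-linked genes, Cdkn1c and Hoxd9.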

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

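The tests with chromosome medians removed were chosen after the data were seen, and the others were planned. Under settings other than leaving out a library, 4920 gene results kept their side of the threshold, 355 newly passed and 208 no longer passed. Of the list results 1275 were kept, 36 newly passed, 58 no longer passed, 2 moved and 1 reversed. A change of direction in a result that passed in neither setting was counted as kept, so direction can differ among the kept results. With 1 library left out the gene results came to 3611, 71 and 557, and the list results to 929 kept, 21 newly passing, 21 no longer passing and 1 moved. The cause was not tested unless named.

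The calls between KO_EV and HET_EV (1235) numbered 3306 with array weights and 2284 with DESeq2, and 763 at a minimum change of 2-fold, which by construction leaves fewer genes. The calls between KO_TR4-2 and KO_EV (69) numbered 3929 with array weights, 759 with DESeq2, 26 with edgeR, 42 with a filter at 5 CPM, 40 with only the groups compared, 44 at a pseudocount of 0.1 and 43 with chromosome medians removed. Those between KO_TR4-2 and HET_EV (1063) numbered 3256, 2122 and 703 with array weights, DESeq2 and a minimum change of 2-fold, and 705 with only the groups compared. Those between KO_EV and the mean of the other groups (366) numbered 3617, 1362 and 231 under the same 3 settings, and a fit of only the groups compared does not apply because all 9 libraries are compared. Opposite calls (38) numbered 1355 with array weights, 288 with DESeq2, 9 with edgeR, 18 with a filter at 5 CPM, 6 with only the groups compared, 18 at a pseudocount of 0.1 and 23 with chromosome medians removed. Array weights ran from 0.278 (KO_TR4-2 clone 8) to 3.58 (KO_TR4-2 clone 18), so that fit leans on a few clones. In simulated data DESeq2 called 45 unchanged genes where limma called 3.

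Leaving out 1 library gave 397 to 1627 calls between KO_EV and HET_EV, 2 to 175 between KO_TR4-2 and KO_EV, 402 to 1226 between KO_TR4-2 and HET_EV, 71 to 661 between KO_EV and the mean of the others, and 0 to 83 opposite calls. Each such fit leaves 1 group with 2 clones. The lists that passed between KO_EV and HET_EV (10) numbered 1 with an estimated correlation and 6 to 11 with 1 library left out, and between KO_TR4-2 and KO_EV (5) they numbered 0 with an estimated correlation, 0 with fry and 4 to 5 with 1 library left out. The interferon list kept its median of 2.18 log2 between KO_EV and HET_EV but did not pass with an estimated correlation (adjusted p = 0.47) or fry (adjusted p = 0.056), and its median ran from 1.40 to 2.78 with 1 library left out. Between KO_TR4-2 and KO_EV its median of -1.27 did not pass under the same 2 tests (adjusted p = 0.85 and 0.53) and ran from -1.74 to -0.36. The Rev3l difference between KO_EV and HET_EV passed with array weights (-0.81 log2, adjusted p = 0.036) and ran from -0.95 to -0.66 with 1 library left out. The Hox list between KO_EV and HET_EV reversed from a median of -0.06 to 0.037 log2 when libraries were rescaled to an equal sum (adjusted p = 0.035), with 1 of its 16 members called higher and 4 lower in both settings. This rescaling moved the median gene of that contrast by 0.10 log2, from -0.0067 to 0.095, the largest shift under any scaling tried, and relative to the median gene the Hox median was -0.05 and -0.06, so the shift makes the reversal.

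No paired analysis was made, because the clone numbers were taken to mark separate clones and not to pair the groups. At this depth 1 read corresponds to at most 0.0287 CPM, so differences below that level were not detectable in a single library.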

Other observations

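The splits of the libraries were planned, and the tests of the interferon list, the chromosome 5 block and the whole chromosomes were chosen after the results were seen.

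Whole chromosomes differed between KO_EV and HET_EV. Of the 912 tested genes on chromosome 7, 81.8% lay higher in KO_EV (median 0.46 log2), and the median was higher in 15 of its 15 bins of 10 Mb. On chromosome 12 the median was -0.44 log2 (12 of 12 bins lower, and -0.29 without HET_EV clone 8) and on chromosome 18 it was -0.42 (9 of 9 bins lower). The changes of single genes given above include such shifts unless chromosome medians were removed. Part of a gene's change may therefore be that of its chromosome. In KO_TR4-2 against HET_EV the chromosome 7 median was 0.30 log2, and 0.14 without KO_TR4-2 clone 8. Relative to the HET_EV mean it was 0.13 and 0.17 in clones 18 and 21 and 0.59 in clone 8, so it rests largely on that clone. Between KO_TR4-2 and KO_EV the largest medians were 0.28 on chromosome 8 and 0.24 on chromosomes 4 and 17, and -0.24 on chromosome 11. The chromosome 17 value was 0.38 without KO_EV clone 15 and 0.14 without KO_EV clone 3. Other splits of these 6 libraries gave chromosome medians of up to 0.47, but on chromosome 14. Relative to the HET_EV mean, chromosome 4 lay at -0.09 to 0.09 in KO_EV and 0.21 to 0.30 in KO_TR4-2. Chromosome 8 lay at -0.29 to -0.08 and -0.03 to 0.16, and chromosome 11 at 0.08 to 0.14 and -0.17 to -0.12. On chromosome 17 the groups overlapped, at -0.30 to 0.19 and 0.06 to 0.18. Medians of this size thus also arise between clones, though not shown for chromosomes 4, 8 and 11.

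Xist stood at 0.134, 50.9 and 75.4 CPM in KO_EV clones 15, 3 and 4 and at 262 to 341 in KO_TR4-2, so the KO_EV clones are not alike in this gene. Between clones of a group the correlation of log2 values across genes ran from 0.93 to 0.99, highest for KO_TR4-2 clones 18 and 21 (0.99), while KO_TR4-2 clone 8 reached 0.94 and 0.93 with these. In KO_EV, clones 3 and 4 reached 0.98 with each other, and clone 15 reached 0.94 and 0.96 with these. The tests count the clones of each such pair as independent, which was not tested. Without any 1 clone of these pairs the calls between KO_TR4-2 and KO_EV numbered 2 to 5. They numbered 98 without KO_EV clone 15 and 175 without KO_TR4-2 clone 8, so this contrast leans on the 2 pairs. The first principal component (38.9% of the variance) set HET_EV apart from the other groups.

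For each pair of groups the 6 libraries allow 10 splits, too few for a share under 0.05. The real split gave 1235 calls between KO_EV and HET_EV against at most 1 in another split, 69 between KO_TR4-2 and KO_EV against at most 5, and 1063 between KO_TR4-2 and HET_EV against at most 4, each being the 1 split of 10 with the most. For KO_EV against the mean of the other groups, 2 of 100 splits, the real one among them, gave at least as many calls as its 366. At 0.05 this argues against all 9 libraries being alike. It does not show 3 distinct groups, since a split that breaks up a distinct HET_EV adds to the spread and loses calls. A drawn split that set KO_EV clones 3 and 4 with KO_TR4-2 clone 8 gave 195. Nor do the splits show a difference of KO_EV by itself, since the count also depends on HET_EV and KO_TR4-2 being kept apart. With the 3 KO_EV clones kept together and the other 6 regrouped, the 9 regroupings gave 5 to 32 calls. Regrouping leaves each estimated change as it was and only adds the difference between HET_EV and KO_TR4-2 to the spread. These counts therefore cannot decide whether KO_EV differs by itself. The highest other, with 912 calls, points to a structure of the samples, since HET_EV against the mean of the other groups gives 1567 calls.

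The higher interferon list in KO_EV was weighed against 3 other explanations. A contribution of KO_EV clone 3 alone is argued against by a median of 1.40 log2 without it, with both remaining clones above all HET_EV clones. Shifts of whole chromosomes are argued against by their size, the largest chromosome median being 0.46 log2. Removing the chromosome medians, which left a list median of 2.22 log2, could therefore not have brought it near 0. A different origin of the HET_EV cells cannot be told apart from genotype, because KO_TR4-2 also stood 0.86 log2 above HET_EV. For the lower list in KO_TR4-2 than in KO_EV, the median was -0.36 log2 without clone 3, with 59 of 67 members still lower and a list mean difference of -0.56 against SDs of 0.37 (KO_EV) and 0.24 (KO_TR4-2), so how much of it clone 3 makes cannot be told apart from an effect of the construct with 2 clones left. Loss of polymerase zeta, the difference that the labels name, stays open, since origin and genotype coincide in the comparisons with HET_EV. KO_TR4-2 and KO_EV both lack Y-linked transcripts, but their comparison does not settle it either, as the part of clone 3 cannot be told apart.

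The block on chromosome 5 in KO_TR4-2 was weighed against 2 explanations. A scaling difference is argued against, since it would shift the surroundings, and the 28 genes within 5 Mb had a median of 0.20 log2, although the 5 on the right had 0.97. Differences between clones regardless of group cannot be told apart from a difference between the groups, because 10 splits are too few for a share under 0.05. The real split was the 1 with the largest median of 8 neighbouring genes, at 2.02 log2 against at most 1.57 in another. A gain of copies of this region, shared by the 3 KO_TR4-2 clones, may explain it and was not tested, since no DNA was measured.

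The whole-chromosome shifts between HET_EV and KO_EV were weighed in the same way. Differences between clones regardless of group cannot be told apart from a difference between the groups, because 10 splits are too few for a share under 0.05. The real split was the 1 with the largest chromosome median, at 0.46 log2 against at most 0.39 in another. Clones of a group also differed: relative to the HET_EV mean the chromosome 14 median was -0.44 and -0.40 in KO_TR4-2 clones 18 and 21 and 0.45 in clone 8, and that of chromosome 9 was -0.16 in HET_EV clone 4 and 0.28 in HET_EV clone 8. On chromosome 7 the HET_EV clones lay between -0.02 and 0.01 and the KO_EV clones between 0.36 and 0.57. After correction for transcript GC content and length the chromosome 7 median was 0.42. Differences in chromosome number between the lines may explain them, a hypothesis that was not tested and that would be confounded with origin.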
